A study of Sphingomonas sp. LH128 with 6 samples.

How the data were processed

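RNA from 3 nonstarved and 3 starved samples of Sphingomonas sp. LH128 was hybridised to custom one-colour Agilent arrays. Per the labels' protocols, cultures were grown in triplicate on glucose at 2 g per litre to an OD600 of 0.5, washed in magnesium sulfate and kept in it at 20 °C for 6 months. The protocol gives its concentration as 0.01 M and the design text as 0.01 mM, and which is right stays open. Per the labels' protocols, RNA was extracted from triplicate tubes of each condition with a column kit, and 4 µg was reverse transcribed with random primers and cyanine-3-labelled dCTP. The labels do not describe whether genomic DNA was removed. The p-values of comparisons between the groups measure the spread between these tubes.

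The deposited scanner files hold the spot brightness as intensity on a linear scale. Per the file headers they were made with Agilent Feature Extraction 10.7.3.1, and all 6 arrays lay on 1 slide read in 1 scan. The processed signal is background-subtracted and detrended within each array, per the file headers, and is not scaled between arrays. Each array had 12863 spots for coding sequences, of which 0 were saturated and 2 to 7 were marked as outliers and left out. The authors also deposited a value table on the log2 scale, whose scale, centring and direction are not stated in the sources used here. Its 6625 rows followed the quantile-normalized log2 processed signal, centred on the median of each row over the arrays (r = 0.998, slope 1.01), so that a higher value is a brighter signal. Its column medians were −0.04, −0.04 and −0.03 for the nonstarved and 0.07, 0.07 and 0.10 for the starved replicates. It leaves out 408 coding sequences of the array, of which 357 were tested here. There were 0 columns of other samples.

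The main values were log2 of the processed signal minus the 75th percentile of each array. Spots of a probe were averaged, then the probes of a coding sequence, and a probe that lacked a value on an array was dropped where another remained. A coding sequence was tested if at least 1 probe was well above background on all arrays of a group. Starved and nonstarved samples were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with tables read by data.table, version 1.17.8. P-values were adjusted by the Benjamini-Hochberg method over the coding sequences tested, with a threshold of 0.05. In simulated data for 6980 coding sequences, 50 were changed by each of several known sizes and the rest were left unchanged. The test recovered 18% of changes of 0.5 log2 units, 72% of 1, 92% of 2 and 96% of 3. It made 7 false calls and 0 with the wrong sign. The simulation had few changes and no common shift, unlike the data, so these rates need not hold for the main comparison. The number of arrays limits the precision.

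The groups, tests and most alternatives were fixed before the data were examined. They included 33 lists of genes by function and a rule for named genes: the largest rises and falls with an adjusted p under 0.05 and no overlap between groups, members of each list, and a set of stress and housekeeping genes. Because the files pair no coding sequence with a gene name, the lists could not be matched and their set tests were not run. The rule was cut down to the 2 largest rises and the 2 largest falls, without its requirement of a name. Analyses by position, by level in nonstarved cells and by probe were chosen after the data were seen. Neighbours were taken in order of start, close ones less than 50 bp apart. Runs hold at least 5 close coding sequences on one strand, and regions come from windows of 10 coding sequences compared with 1000 shuffles of their order.

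The alternatives were other scalings, other background corrections, the deposited value table, other filters and probe rules, a variance trend, blocks for replicate number and slide row, and leaving out each array. The scanner files have no mean spot signal, so the planned normexp correction was replaced by one on the median signal with an offset of 50. A block for slide or scan could not be fitted with 1 slide and 1 scan, and the row of the slide was used instead.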

Results

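Sphingomonas sp. LH128 is a soil bacterium that degrades phenanthrene and other polycyclic aromatic hydrocarbons. Its transcript levels were measured in cells starved for 6 months and in nonstarved cells. Cells were grown on glucose to the exponential phase, washed, and kept without a carbon source in magnesium sulfate solution at 20 °C. The nonstarved group was freshly grown cells washed in the same salt solution. Each group comprised 3 samples from separate tubes, each hybridised to 1 one-colour array, and all 6 arrays lay on 1 slide. The arrays carried probes for 7033 coding sequences, of which 5630 had 2 probes (a and b) and 1403 had 1. The array names each coding sequence by its start and end in an assembly that the sources used here do not name. No gene name was therefore assigned, and positions are given in those coordinates. All 7033 lengths were multiples of 3, and the coordinates ran from 32 to 6493932.

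The signal of the starved arrays was more even across coding sequences than that of the nonstarved arrays. Dim probes were brighter and bright probes took a smaller part of the total. The 5th percentile of the processed signal was 2.82 ± 0.22 units (SD, n = 3) in nonstarved and 56.2 ± 32.1 units (SD, n = 3) in starved samples. The median was 54.7 ± 3.7 units (SD, n = 3) in nonstarved samples and 153.5 ± 78.7 units (SD, n = 3) in starved samples. The brightest 1% of spots carried 39.1% ± 0.26 of the total signal in nonstarved and 23.1% ± 7.4 in starved samples (SD, n = 3 each). The interquartile range narrowed from 3.53 ± 0.10 to 1.32 ± 0.19 log2 units (SD, n = 3 each). Spots well above background made up 78.9% ± 1.8 of all spots in nonstarved and 98.6% ± 2.4 in starved samples (SD, n = 3 each). For each of these 5 measures the groups did not overlap, and the two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 samples allow. The 75th percentile used for scaling did not separate the groups (186.1 ± 10.3 against 245.9 ± 114.5 units, SD, n = 3 each, exact permutation p = 0.4).

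**Figure D1:**
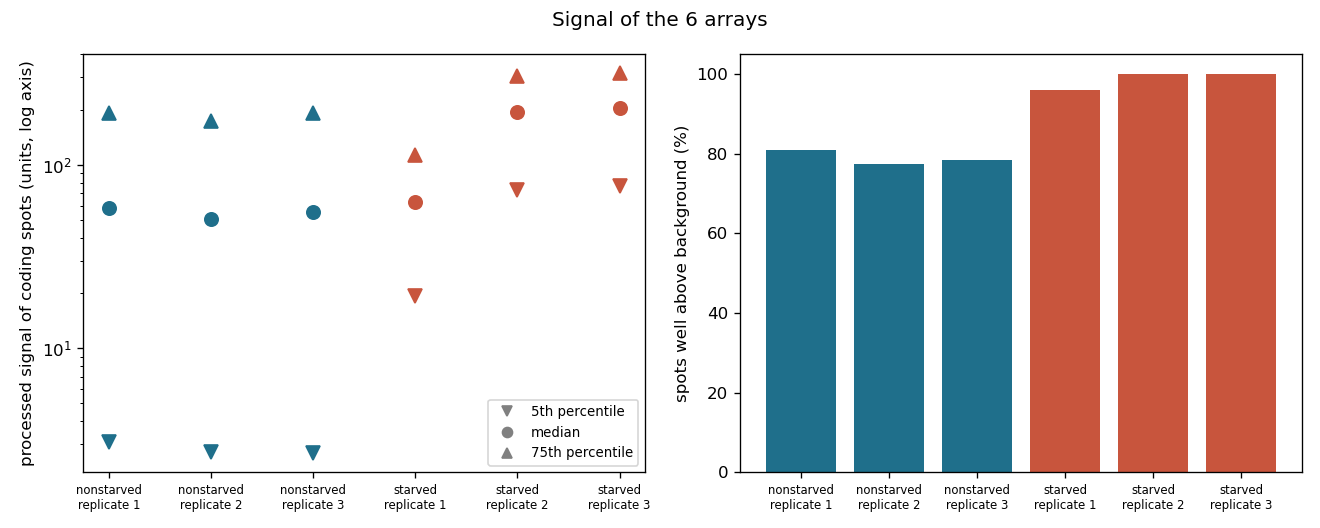
Left, the 5th percentile, median and 75th percentile of the processed signal of coding spots on each array (units, log axis); right, the percentage of spots well above background, with nonstarved arrays in blue and starved arrays in red. The 5th percentile lay between 2.67 and 3.07 units on nonstarved arrays and between 19.2 and 76.7 units on starved arrays.

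Starved replicate 1 stood apart from the other starved samples. Its median signal was 62.9 units, against 194.4 and 203.4 units in starved replicates 2 and 3. Across coding sequences, its level correlated with that of starved replicates 2 and 3 at r = 0.911 and 0.931. Starved replicates 2 and 3 correlated at 0.987, and nonstarved pairs at 0.983 to 0.987. Coding sequences are not independent replicates, so these correlations describe the arrays only. Correlations between the groups ran from 0.490 to 0.626, and the highest belonged to starved replicate 1.

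The main comparison asked which coding sequences changed level between nonstarved and starved cells. Coding sequences with a high signal in nonstarved cells mostly fell, and those with a low signal mostly rose. Of 6980 coding sequences tested, 4617 (66.1%) rose, 1465 fell and 898 did not pass an adjusted p of 0.05 in limma. The largest fall was −8.39 on the log2 scale, and the largest rise among coding sequences well above background on at least 1 nonstarved array was 5.75. The median standard error was 0.17 (n = 3 per group). Of the 4760 that changed at least 2-fold, 3809 rose and 951 fell. The groups did not overlap for 6225 coding sequences (89.2%, against 10% by chance).

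The direction of change rested in part on the scaling between arrays. With each array set to its 75th percentile, the median coding sequence rose by 1.22 log2 units, and 75.9% of the changed coding sequences rose. Under quantile normalization the median shift was 0.18, with 2816 rising and 2350 falling (54.5% rose). Under scaling to the array median, 53.9% of changed coding sequences rose, and with no scaling 85.9% rose. Scaling to the array median left a shift of 0.17, and 2299 coding sequences then rose and 1921 fell by at least 2-fold. Under all 4 of these scalings, 618 coding sequences fell and 2228 rose, while 4134 did neither. The 618 are limited by the comparison with no scaling, in which only 629 fell. The 618 had a median signal of 743.7 units in nonstarved and 144.2 units in starved samples. The 2228 had 17.7 units in nonstarved and 154.1 units in starved samples.

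Change followed the level in nonstarved cells. Coding sequences were divided into deciles by nonstarved replicate 1, and their change was taken against nonstarved replicates 2 and 3, with limma calls from a fit that left replicate 1 out. In the dimmest decile all 698 rose, from a median of 4.78 to 88.6 units. The median change there, 3.90 log2 units (SD 0.77 over coding sequences), is no measured size, since 467 of the 698 were not well above background on any nonstarved array. In the eighth decile 228 rose and 253 fell, with a median change of −0.06 (SD 0.93). In the brightest decile 576 fell and 18 rose, with a median change of −2.13 (SD 1.48), from 913.6 to 287.6 units. The median in the brightest decile was −1.95, −2.20 and −2.19 in starved replicates 1, 2 and 3. Of the risen coding sequences, 544 were not well above background on any nonstarved array, so that only a bound on their rise is known. Where a probe had to be well above background on all 6 arrays, 3605 of the 4617 rises remained. None of the fallen coding sequences was below background on all starved arrays. This was nearly set beforehand, since 95.8%, 99.93% and 99.98% of spots were well above background on starved replicates 1, 2 and 3. If part of the even starved signal is not their own transcript, the sizes of the falls are not known either.

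**Figure D2:**
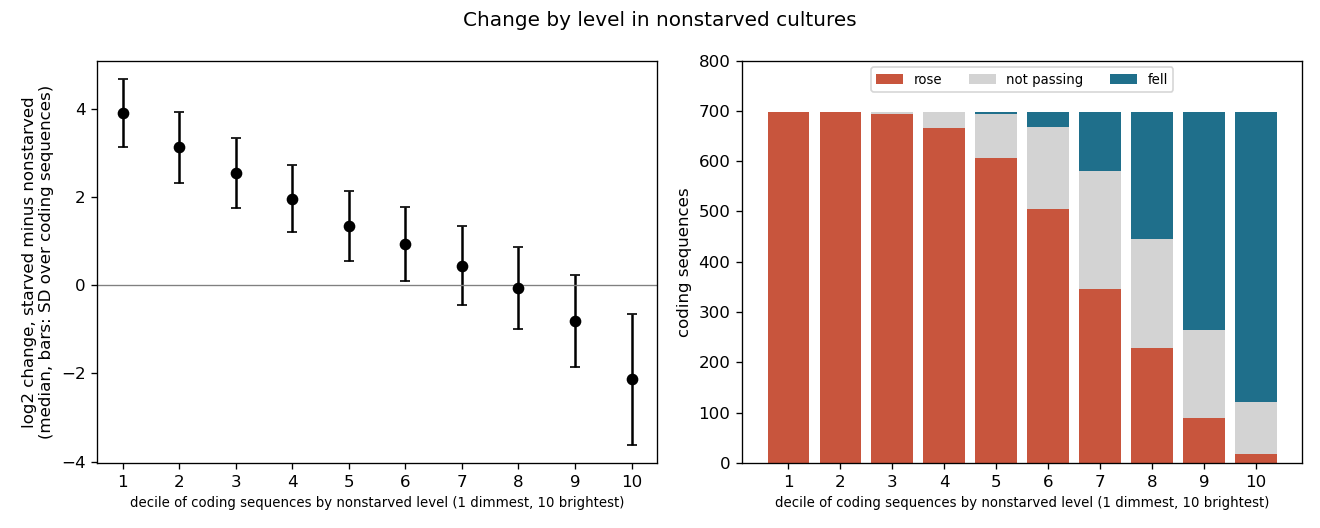
Left, median log2 change (starved minus nonstarved) for deciles of the coding sequences ranked by their level in nonstarved replicate 1, with bars for the SD over 698 coding sequences; right, the number in each decile that rose, fell or did not pass in a fit without nonstarved replicate 1. The median went from 3.90 in the dimmest decile, where 467 of 698 were not above background in nonstarved samples, to −2.13 in the brightest.

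The largest fall was that of 1033798_1034577, a forward coding sequence of 780 bp at 1033798 to 1034577. It fell by 8.39 ± 0.21 log2 units (SE, n = 3 per group, limma adjusted p = 4.46e-07), with changes of −8.04 and −8.74 at its probes. Probe a read 24858 to 26331 units on the nonstarved arrays and 78.3 to 162.2 units on the starved arrays. The reverse coding sequence 2140472_2139903 (570 bp, 2139903 to 2140472) fell by 6.73 ± 0.59 (SE, n = 3 per group, limma adjusted p = 1.71e-05), with changes of −6.62 and −6.84 at its probes. The SD between its starved replicates was 1.35 log2 units, against 0.20 between nonstarved replicates, and without starved replicate 1 its change was −7.51. The forward coding sequence 4298851_4299372 (522 bp, 4298851 to 4299372, 1 probe) rose at least 16.6-fold, since it was not well above background on any nonstarved array (limma adjusted p = 4.46e-07, n = 3 per group). The forward coding sequence 5440493_5440855 (363 bp, 5440493 to 5440855, 1 probe) rose at least 14.1-fold by the same measure (limma adjusted p = 6.99e-07, n = 3 per group). In each bound the starved mean is set against the lowest nonstarved signal that counted as well above background, or the probe's own if higher. Both bounds hold for 75th-percentile scaling and would be lower under scalings with a smaller shift: the fitted log2 rises of 4298851_4299372 and 5440493_5440855 were 5.21 and 4.91 under array-median scaling and 4.62 and 4.01 under quantile normalization. With normexp on the median signal, whose offset compresses low signals, these rises were 2.12 and 1.79, against fitted values of 6.26 and 5.95 in the main comparison.

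Large falls were found mainly among short coding sequences. Of 65 that fell at least 16-fold, 20 were among 1216 tested of at most 300 bp. Another 28 were among 1852 of over 300 and at most 600 bp. The rest were 14 among 2499 of over 600 and at most 1200 bp, and 3 among 1413 longer than 1200 bp. The percentage that fell in these length classes, from the shortest, was 22.6%, 24%, 19.7% and 17.9%. No test was made of these length classes. Both strands changed alike in number, with 2301 of 3436 forward and 2316 of 3544 reverse coding sequences rising, and 723 and 742 falling.

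Neighbouring coding sequences on the same strand had similar log2 changes. Across 2311 pairs less than 50 bp apart on one strand, the log2 changes correlated at r = 0.549, against 0.287 for 1874 same-strand pairs farther apart and 0.016 for 2794 pairs on opposite strands. The difference between close same-strand and opposite-strand pairs gave a permutation p of 1e-04, the smallest the shuffles could give. The nonstarved levels of close same-strand pairs correlated at 0.411, against 0.00397 for opposite strands (permutation p = 1e-04, the smallest). For the starved levels these correlations were 0.121 and 0.074, a difference that did not pass (permutation p = 0.146). With starved levels more even, the change in part mirrors the nonstarved level. The similar changes therefore do not by themselves show that neighbours responded together to starvation. Probes a and b correlated less on starved arrays, with r of 0.452 ± 0.019 across coding sequences on nonstarved and 0.180 ± 0.015 on starved arrays (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). Probe means lay over 4-fold apart for 1986 coding sequences in nonstarved and 869 in starved samples. The lower r therefore does not mean a wider gap between probes.

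**Figure D3:**
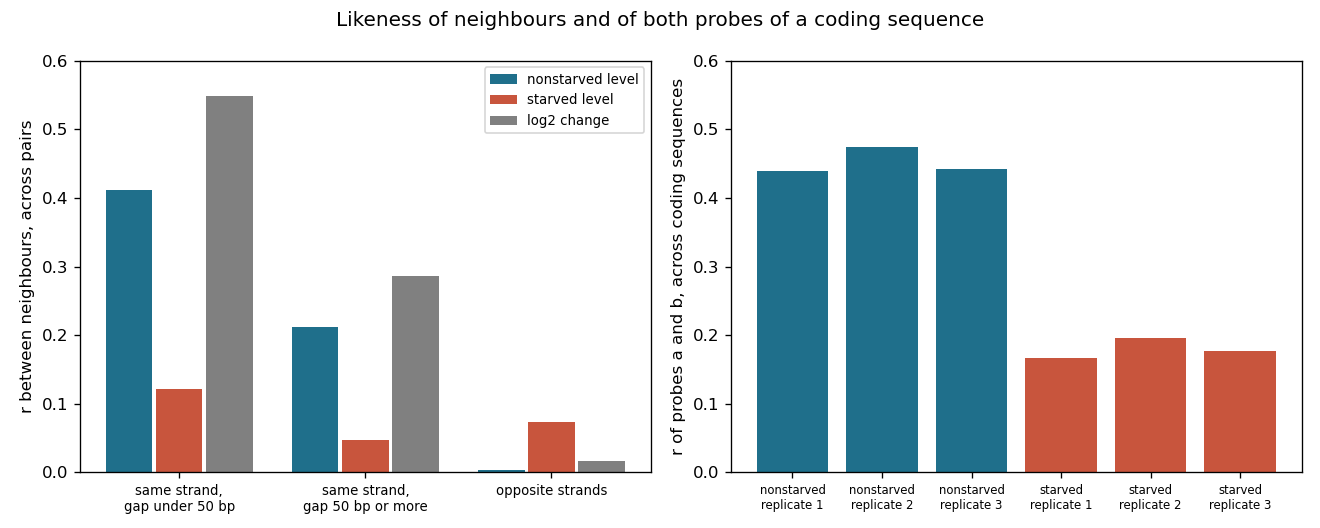
Left, correlation between neighbouring coding sequences in nonstarved level, starved level and log2 change, by strand and distance; right, correlation of probes a and b across coding sequences on each array. Close same-strand neighbours reached 0.411 in nonstarved and 0.121 in starved level, and the probe correlation lay between 0.439 and 0.474 on nonstarved and between 0.167 and 0.196 on starved arrays.

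Among 99 runs of at least 5 close coding sequences on one strand (653 coding sequences in all), every member fell in 2 runs and every member rose in 33. Shuffled positions gave means of 0.014 and 7.75 runs, and the permutation p was 0.001 for both, the smallest that 1000 shuffles could give. Under quantile normalization every member fell in 3 runs and rose in 5, against shuffle means of 0.189 and 0.478 (permutation p = 0.001 for both). The shuffles treat neighbours as independent, which their nonstarved levels were not. These p-values therefore do not show that runs responded to starvation as units, and they do not measure the spread between samples. The runs and regions named here were chosen after their values were seen. The strongest fall was in a reverse run of 9 coding sequences at 746710 to 750499. All 9 fell, with a median of −3.42 log2 units and a median signal of 1579 units in nonstarved and 159.5 units in starved samples. Its medians in starved replicates 1, 2 and 3 were −2.68, −3.98 and −3.78, and under quantile normalization the median was −3.91. In a reverse run of 5 at 3346169 to 3352146, 4 fell and 1 rose (median −2.47). Under quantile normalization all 5 fell, with a median of −2.89. All 6 members of a forward run at 3803088 to 3808386 fell (median −1.24), of which 5 fell under quantile normalization (median −1.65).

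With 75th-percentile scaling, the runs with the highest fitted rises had low signals in nonstarved samples, though under quantile normalization some other runs rank above 2 of them. A forward run of 5 at 1183425 to 1185332 rose throughout. Since only 2 of its 5 members were well above background on all nonstarved arrays, its fitted median of 3.70 log2 units is no measured size. It was 1.78 over the members well above background on all 6 arrays, and 0.80 with normexp on the median signal. A reverse run of 6 at 48731 to 54408 rose with a median of 3.51, and 5 of its members were well above background in nonstarved samples. A forward run of 6 at 5121186 to 5125772 rose with a median of 3.25, and 4 of its members were well above background. With normexp the medians of these last 2 runs were 1.36 and 0.84. The median nonstarved signals of these 3 runs were 6.45, 10.9 and 13.1 units. Under quantile normalization the medians of the 3 runs were 1.36, 2.03 and 1.35. The members that rose under it were then 4 of 5, 5 of 6 and 5 of 6, and 1 member of the run at 48731 to 54408 fell.

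Medians over windows of 10 neighbouring coding sequences picked out 2 regions of low values and 0 of high values. The first, 742542 to 760474 (17.9 kb), held 26 coding sequences, of which 19 fell and 6 rose. Its median change was −3.36 log2 units, from a median signal of 1381 to 139.7 units (permutation p = 0.002, two-sided, over the whole length). It includes the run of 9 that fell. The second, 2525070 to 2532675 (7.61 kb), held 12 coding sequences, of which 7 fell and 4 rose (median −1.45, permutation p = 0.048). Under quantile normalization the medians of these regions were −3.04 and −2.01, with 19 and 8 members falling and 2 rising in each. The p-values of the regions rest on shuffles of the same kind as for the runs and have the same limits.

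**Figure D4:**
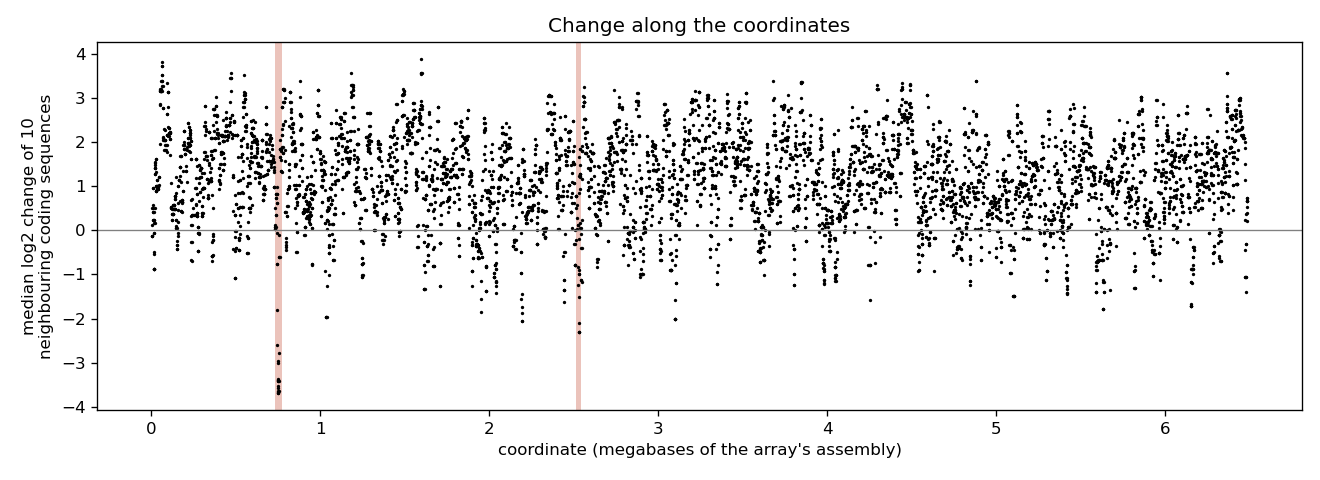
Median log2 change (starved minus nonstarved) of 10 neighbouring coding sequences against position in megabases of the assembly used for the array, with the 2 low regions shaded (drawn slightly wider than they are). The shaded regions lie at 742542 to 760474 and at 2525070 to 2532675, with median changes of −3.36 and −1.45 over their members.

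The probes of a coding sequence did not always change the same way. Of 4948 changed coding sequences with both probes, 519 (10.5%) had probes that differed in sign. The log2 changes of probes a and b correlated at 0.644 across coding sequences. Both probes passed in one direction for 2932 that rose and 772 that fell, and passed in opposite directions for 380. Since the named coding sequences cannot be tied to functions here, no pathway was tested.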

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

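The tests in this part were chosen after the result was seen, except the count over splits of the samples and, for starved replicate 1, the tests of nonstarved-like RNA and of brightness, whose predictions were written before their values were known. Of the 10 ways to split the 6 arrays into 3 and 3, only the real one gave as many as 6082 changed coding sequences. The highest count of any other split was 0, and 10 splits are too few for a share under 0.05.

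Several kinds of the array maker's control probes, which the comparisons do not use, were brighter on starved replicate 3 than on any nonstarved array. On that array the median background-subtracted signal was 48.3 units for E1A probes, 41.7 for DCP probes, 17.0 for ETG probes and 32.2 for eQC probes. Negative-control spots there had a median of −0.429, above every nonstarved array yet below 0. The eQC medians of 1.54 on starved replicate 1 and 0.376 on starved replicate 2 exceeded the nonstarved arrays too. They stayed under 5.90 and 4.96 units, the level 3 median absolute deviations above the median of the negative controls of those arrays. The bright-corner controls went the other way, with 268.9 ± 40.0 units on nonstarved and 36.0 ± 20.0 units on starved arrays (SD, n = 3 each, exact permutation p = 0.1, the smallest possible).

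For the control probes of starved replicate 3, stray light or background left after subtraction was argued against. Negative-control spots rose by 1.77 units over the other starved arrays, while E1A probes rose by 41.3. Both signals are background-subtracted, so the background before subtraction was not compared. An additive signal on all probes was tested but not settled. The 5th percentile of coding spots exceeded that of starved replicate 2 by 3.99 units, against 42.9 for E1A probes. That percentile also varied without the control probes: it was 19.2 and 72.7 units on starved replicates 1 and 2, with E1A medians of 8.60 and 5.40. A small difference between starved replicates 2 and 3 therefore cannot exclude an added signal. What made these control probes bright stays open, and no biological explanation was tested.

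The starved arrays carried a more even signal over coding sequences, with a lower correlation of probes a and b. Background, or nonspecific binding that reaches control probes too, was argued against on starved replicates 1 and 2. There the median E1A probe rose by 0.181 and −0.00327 of the rise of the 5th percentile of coding spots. E1A values are background-subtracted signal and coding values processed signal, here and in the comparisons of starved replicate 3. E1A probes lie outside the LH128 genome, so they cannot show LH128 material bound to the wrong coding probes. On starved replicate 3, where the control probes themselves were bright, that ratio was 0.578, while the 5th percentile of its coding spots was 76.7 units, against 72.7 on starved replicate 2. An even target such as chromosomal DNA in the labelled material may account for the even signal. The difference between nonstarved and starved levels correlated between probes at 0.644, better than the nonstarved level alone (0.457). Taking a difference removes each probe's own brightness whatever the cause, so this rise does not favour an even target. A transcript pool of near-equal levels after starvation would also give the low probe correlation on the starved arrays (0.178 against 0.457), and nothing measured here separates these explanations.

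Starved replicate 1 stood between the nonstarved and the other starved arrays. Lower brightness alone was argued against: over 1298 coding sequences above 100 units on all arrays, its difference from starved replicate 2 had 2.49 times the largest SD of nonstarved pairs, against 0.672 for starved replicates 2 and 3. The row of the slide was not settled. The row differences of the groups correlated at r = 0.0436, where a row effect alone would give a high r. Replicate 1 of both groups also lay in slide column 2, apart from replicates 2 and 3, so row and column effects could cancel. A larger remaining share of RNA like that of nonstarved cells may account for it, since its difference from starved replicate 2 followed that of nonstarved arrays from starved replicate 3 (r = 0.417, slope 0.102). A smaller amount of an even target on that array could give the same pattern. Its 5th percentile was 19.2 units, against 72.7 and 76.7 on starved replicates 2 and 3. These explanations were not told apart, and whether any such RNA came from surviving cells or from handling was not tested.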

How the results depend on the processing

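The normexp corrections on the median signal, the block for slide row and the count by both probes were chosen after seeing the data. Counts were held to 1.5 times the main count and the share that rose to its binomial confidence interval, and the signal difference to the spread between replicates; 88 of these values stayed within and 23 moved. The 4 named coding sequences kept their direction and passed wherever tested, though not their size: with normexp 4298851_4299372 rose by 2.12 and 1.97 log2 units and 5440493_5440855 by 1.79 and 1.48 (percentile and quantile). Of all values for single coding sequences, runs, neighbour correlations and the median shift, 184 stayed and 74 moved. A single coding sequence counted as staying if it kept its direction and passed, whatever its size. Some values could not move, since scaling by a constant per array leaves neighbour correlations as they were. The median over probes repeats the main values too, among the 88 as well as the 184. Neither count is therefore a measure of robustness. Quantile normalization gave 2816 rising, 2350 falling and 54.5% rising; 560 coding sequences that rose in the main comparison then fell and 14 that fell then rose. Array-median scaling gave 2650 falling and 53.9% rising, no scaling 629 and 85.9%, and the percentile over probes above background on all arrays 81.0%. The deposited value table gave 2725 rising, 2264 falling and 54.6%. Normexp gave 2063 changed at least 2-fold and 70.4% rising after percentile scaling, and 1573, 2793 rising and 56.0% after quantile normalization; of those 1573, 706 rose and 867 fell, against 3809 and 951 in the main comparison. Requiring all 6 arrays above background gave 71.1% and the brightest probe 70.5%. Counting only where both probes passed in one direction, which leaves coding sequences with 1 probe out, gave 3704 changed, 2932 rising, 772 falling, 2813 at least 2-fold and 79.2%. The cause was not tested for the others.

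Leaving out each array in turn gave 5855 to 6286 changed, 4716 to 4814 at least 2-fold, 4473 to 4742 rising, 1356 to 1544 falling, 75.4% to 76.9% rising, and a difference of 19.0 to 21.1 percentage points in spots above background. Without starved replicate 1, 6286 changed, 4742 rising and 1544 falling. Replicate numbers did not pair the samples (r of −0.0436, 0.0862 and −0.112 for replicates 1, 2 and 3, and 1 of the 3 correlated best with its own number), and the replicate block gave 6019 changed, 4590 rising and 1429 falling. The slide row block gave 6060. The planned normexp on the mean signal, the block for slide or scan and the gene lists were not run; the median over probes moves nothing with at most 2 probes each. Nonstarved signal near background limits the 544 rises known only as bounds.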

Other observations

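Of the tests in this part, the one on dilution and the bright coding sequences was chosen after the result was seen. The test across probes was chosen after the result on dilution, with its prediction written before its own value was known.

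Among the 100 coding sequences brightest on both probes in nonstarved cells, 99 fell, 0 rose and 1 did not pass in limma, and 34 fell at least 16-fold. Their median change was −3.56 log2 units, from −8.39 to −0.65.

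Some coding sequences were bright on starved arrays by both of their probes. There were 36 with both probes in the top 5% of the starved level, against a mean of 14.1 over 10000 shuffles (permutation p = 1e-04, the smallest the shuffles could give). On the nonstarved arrays there were 89, and 8 belonged to both sets. Of the 36, 19 rose, 8 fell and 9 did not pass, and 6 rose at least 2-fold beyond the median shift.

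A hypothesis was that the falls of the 100 brightest could come wholly from dilution of the nonstarved pool by an even target. Their changes varied with an SD of 1.20 log2 units, against a median SE of 0.21, and probes a and b correlated at 0.671. The prediction had taken such spread and likeness as evidence against dilution, which was wrong. A wholly even starved level would leave changes that mirror the nonstarved levels, whose SD over these 100 was 1.03 and whose probe correlation was 0.581. Those values pass the same bounds, so the test decides nothing.

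A further hypothesis was that some of the nonstarved transcript pattern remains on the starved arrays. The starved level of one probe correlated with the nonstarved level of the other probe of its coding sequence at 0.0912, against 0.0077 for opposite-strand neighbours. This fell between the bounds of 0.05 and 0.1 set for it, so it stays open. By array it was 0.122 for starved replicate 1, 0.068 for starved replicate 2 and 0.071 for starved replicate 3. The same probe on both kinds of array correlated at 0.622, which each probe's own brightness may raise, and both probes on nonstarved arrays at 0.457.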
